A study of Homo sapiens with 4 samples.

How the data were processed

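The study measured N6-methyladenosine (m6A), a methyl mark on adenosines of messenger RNA, in HEK293T cells, an established human embryonic kidney line that grows readily and takes up plasmids well. The assay was MeRIP-seq, in which fragmented polyadenylated RNA is pulled down with an antibody against m6A and sequenced beside a portion kept as input. Per the labels, cells received a construct called dCas13b-M14 together with a guide RNA by polyethylenimine transfection. Cas13b is an RNA-guided RNA nuclease, and a "d" before such a name denotes a form without cutting activity. What M14 stands for is not given in the sources used here. All samples carry the same treatment text, so the labels do not say in what way the group named Ctrl was treated differently from the group named Cas. The 4 libraries were an input and an immunoprecipitation for each of these groups, with 1 library per group and kind. Peak lists of the 2 immunoprecipitation libraries were analysed, and the input libraries entered no comparison here.

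The submitters' processing notes name FastQC, fastp, HISAT2, SAMtools, edgeR and HOMER, with no versions or roles, and the build GRCh38. The peak caller, its threshold, its use of the input and the transcript release are not given in the sources used here. As deposited, each line of a list holds a RefSeq transcript, the first and last position of a peak along that transcript counted from 1, a further position inside the peak whose meaning is not stated, an empty field and a strand that is always plus. The authors' lists carry no read count, score, fold or p-value. Depth is therefore unknown, and a gene without a peak is one with no listed peak, which does not show that its RNA was unmethylated. The design fixed before the data were examined foresaw this and ranked peaks by number and width where no score was given.

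Peaks were compared along the transcript, so that an overlap of at least 1 bp on the same transcript counted as shared (bedtools 2.31.1). Each share was set beside 100 shuffles that moved every peak of a list to a random place on its own transcript. The transcript length for the shuffles was that of its GENCODE release 29 partner or the end of its last peak, whichever was larger. Wilson 95% intervals cover the counting of peaks only. With 1 library per group there is no replicate error, and no p-value or test between groups was computed. Gene names came from a RefSeq gene table of GRCh38.p14, which also gave the gene coordinates. Counts of genes include every gene with a peak, whatever its type, although coding and lncRNA genes had been planned. The expected overlap of independent lists was computed over coding and lncRNA genes.

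Regions and sequence motifs need a transcript model. RefSeq transcripts were paired with GENCODE transcripts by the cross-reference of that release. Of the 11254 transcripts, 10206 had a partner, 10193 of them a single one, and 1101 carried a peak past the partner's end. Regions and motifs were therefore read on the 1859 transcripts whose 5' end lay within 10 nt of that of the RefSeq gene. This restriction and the stop codon window of 200 nt to either side were chosen after the data were examined. The restriction followed exploratory motif profiles that were sharper on those transcripts, and values over all partners are given as an alternative. A peak was placed by its centre. DRACH, the usual sequence context of m6A in mRNA, and its frequent form GGACT were searched inside peaks.

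The 21 gene lists were fixed before the data were examined. For each, the number of members with peaks in Cas only minus that in Ctrl only was ranked among 10000 random lists of the same size with the same numbers of peaks. Such a percentile describes these libraries and is no test of the conditions. Genes were named by a rule also fixed beforehand. It takes the 3 targeted genes, the 10 genes with most peaks in each library alone with ties broken by width, the 5 genes with the largest gain and the 5 with the largest loss in peak number, and list members in order of their widest peak with every m6A writer, eraser and reader. Genes in the second part had to overlap no exon of another gene, a rule applied to the whole partner transcript. This left out genes without a single partner that held every peak, and transcripts with several copies. Some genes that the rule takes, and results that rest on them, are not reported here.

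Tests of transcript length first used only transcripts whose partner held every peak. That set covered 79.9% of the zinc finger list, below the coverage needed, and was widened after its results were seen. Both versions are given. Overlap and list scripts were tested on simulated data: with 70.1% of peaks planted as overlapping, 70.2% were found, and 94.5% of random lists of 60 genes lay within the central 95 percentiles. Alternatives covered the definition of overlap, wider peaks, merged peaks, equal list sizes, gene types, region priority, motif and the numbering of the labelled positions. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.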

Results

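The series examined m6A in HEK293T cells after methylation was directed to positions named YTHDF2-1551, SPEN-3525 and GAPDH-782. The list of the Ctrl immunoprecipitation held 23623 peaks on 10715 transcripts of 10711 genes, and that of the Cas immunoprecipitation held 23134 peaks on 10127 transcripts of 10123 genes. Peaks had a median width of 194 bp in Ctrl (interquartile range 149 to 266) and of 188 bp in Cas (141 to 260). They covered 5273760 bases in Ctrl and 5064954 in Cas. The narrowest peak listed was 100 bp wide in both libraries. There were no replicates, so that every difference below is one between 2 libraries.

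The first comparison asked how the peaks at the targeted genes differed between the libraries. YTHDF2, an m6A reader that promotes decay of methylated mRNA, had 2 peaks in each library, at nearly the same places. SPEN, a large nuclear repressor that binds RNA, had 7 peaks in Ctrl and 5 in Cas. GAPDH, a glycolytic enzyme, had no listed peak in either library.

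YTHDF2 (chromosome 1, 28736624 to 28769775, GRCh38.p14) was listed as transcript NM_016258. Its peaks spanned positions 1909 to 2063 and 2271 to 2404 in Ctrl and 1912 to 2063 and 2301 to 2407 in Cas. By the GENCODE partner the first of each pair lay in the coding sequence and the second in the 3' UTR. Together they covered 289 bases in Ctrl and 259 in Cas. Counted from the start of the coding sequence, position 1551 is transcript position 1913, inside the first peak of both libraries. Counted from the start of the transcript it lay 358 nt from the nearest Ctrl peak and 361 nt from the nearest Cas peak. The labels do not say which numbering was meant, and under neither was the position the centre of a DRACH motif on the partner transcript.

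SPEN (chromosome 1, 15847707 to 15940456) was listed as NM_015001. In Ctrl its peaks lay at 754 to 927, 2512 to 2878, 3348 to 3490, 4421 to 4520, 4602 to 4760, 6399 to 6570 and 11513 to 11810. In Cas they lay at 444 to 910, 2516 to 2866, 4611 to 4820, 6321 to 6560 and 11514 to 11810. All 5 Cas peaks overlapped a Ctrl peak. The Ctrl peaks at 3348 to 3490 and 4421 to 4520 had no Cas partner. The last peak of each library lay in the 3' UTR and the others in the coding sequence. The bases covered were 1413 in Ctrl and 1565 in Cas. Counted from the coding start, position 3525 lay 239 nt from the nearest Ctrl peak and 863 nt from the nearest Cas peak. Counted from the transcript start these distances were 35 and 659 nt. With the coding start moved by the 157 nt difference at the partner's 5' end they were 396 and 725 nt. No peak of either library held the position under either numbering. Among the wider 50% of each list SPEN had 2 peaks in Ctrl and 5 in Cas, which turns the order of the full lists, and YTHDF2 had none. GAPDH lies on chromosome 12, 6534517 to 6538371.

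The second comparison asked how far the m6A peaks of the whole transcriptome were shared. Of the Ctrl peaks, 17895 (75.8%, Wilson 95% interval 75.2 to 76.3) overlapped a Cas peak, against a mean of 27.1% when peaks were shuffled along their transcripts. Of the Cas peaks, 18033 (78.0%, 77.4 to 78.5) overlapped a Ctrl peak, against 27.8% when shuffled. The peaks without a partner numbered 5728 in Ctrl and 5101 in Cas. Of these, 4127 and 4464 lay on transcripts that had a peak in the other library too. Overlapped peaks were wider, with medians of 211 against 144 bp in Ctrl and 201 against 149 bp in Cas. In the narrower 50% of peaks 63.1% of Ctrl and 67.5% of Cas peaks were overlapped, and in the wider 50% 88.6% and 88.5%. The shuffles covered the whole lists and give no level for either width group.

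Most genes with peaks had them in both libraries. These numbered 9584, with 1127 genes in Ctrl only and 539 in Cas only, a ratio of 2.09. In the wider 50% of both lists these were 1525 and 1162, a ratio of 1.31. Among coding and lncRNA genes 9329 had peaks in both, where independent lists would share 3909 if drawn from all 26163 annotated genes of these types, expressed or not. Of the genes in both, 5350 (55.8%) had the same number of peaks, 2320 had more in Cas and 1914 had more in Ctrl. Long noncoding RNAs made up 2.58% of the genes in both (2.28 to 2.91), 11.4% of the Ctrl-only genes (9.72 to 13.4) and 6.49% of the Cas-only genes (4.71 to 8.90). A single peak was all that 70.9% of the Ctrl-only and 84.6% of the Cas-only genes had.

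Genes with peaks in 1 library were compared by transcript length over the 10189 genes with a single GENCODE partner. In the shortest of 4 equal classes (312 to 2173 nt) 330 genes were in Ctrl only and 292 in Cas only. In the longest (5135 to 91667 nt) these numbers were 169 and 29, or 6.64% and 1.14% of the class.

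Among genes that overlap no exon of another gene, the one with most peaks in Ctrl alone was PCLO, which encodes a scaffold of the presynaptic active zone, with 9 peaks over 1770 bases. All 9 had both ends on a 10-base grid. Of all such Ctrl peaks 55.3% were overlapped by a Cas peak, against 83.4% of the other Ctrl peaks. The other Ctrl-only genes named here each had some peak off this grid, although most peaks of PRICKLE2, MBD5 and MAP3K13 lay on it. PRICKLE2, MBD5, MAP3K13, PER2, TRERF1 and ARHGAP31 had 5 each, PER2 being a core repressor of the circadian clock. The peaks of ARHGAP31 were 100 to 110 bp wide, close to the narrowest width listed. SMURF1, a ubiquitin ligase of the BMP pathway, and FBXL18 had 4 each. In Cas alone, MAP7D1 had 4 peaks over 619 bases. OPTN, an autophagy receptor, CC2D1A, the malic enzyme ME1, the cytosolic aconitase ACO1, ZSCAN23 and the lncRNAs HCP5 and KCNQ1OT1 had 3 each. The 3 peaks of KCNQ1OT1 covered 300 bases in all. UTP11, a factor of ribosome assembly, had 2. Among these Cas-only genes, most peaks of OPTN, ME1, ACO1, ZSCAN23 and KCNQ1OT1 lay on the 10-base grid.

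Among genes with peaks in both libraries, the largest gains in peak number, with ties broken by bases covered, were at CELSR2 (2 in Ctrl, 8 in Cas), AKAP13 (7 and 12), KIAA1671 (3 and 8), ATM (3 and 8) and UTRN (7 and 12). CELSR2 encodes an adhesion receptor of the cadherin family, ATM a kinase of the DNA damage response and UTRN a relative of dystrophin. The largest losses were at USF3 (11 and 2), ASXL3 (9 and 1), ZFHX4 (14 and 8), PPARA (8 and 3) and BAZ2B (8 and 3). PPARA encodes a nuclear receptor that regulates fatty acid oxidation, and ASXL3 takes part in chromatin regulation. At USF3 1 of the 11 Ctrl peaks overlapped a Cas peak. Most Cas peaks without a partner at CELSR2 and KIAA1671, and most such Ctrl peaks at USF3, were 100 to 130 bp wide. These widths are close to the narrowest listed. At UTRN the Ctrl peak from 1661 to 2360 overlapped Cas peaks from 1651 to 2000 and from 2091 to 2380. Of the genes with the largest gains and losses, AKAP13, ATM and PPARA were not covered by the check for exons of other genes. That check was applied to genes with peaks in 1 library. ATM and PPARA had no single GENCODE partner, and AKAP13 had a peak past the end of its partner.

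The m6A machinery itself carried peaks throughout. All 9 genes of the list of m6A writers had a peak, 7 of them in both libraries. METTL14, the RNA-binding partner of the methyltransferase METTL3, had 1 peak in Ctrl, at 1354 to 1506 of NM_020961 in the coding sequence, and none in Cas. The centre of that peak lay within 200 nt of the stop codon of the GENCODE partner. WTAP, the adaptor of the complex of METTL3 and METTL14, had 2 peaks in Ctrl and none in Cas. Numbers in Ctrl and Cas were 3 and 3 for METTL3, 2 and 4 for METTL16, 6 and 6 for VIRMA, 5 and 5 for ZC3H13, 3 and 2 for RBM15, 1 and 2 for RBM15B and 1 and 2 for CBLL1. The balance of Cas-only and Ctrl-only members stood at percentile 5.49 of random lists. With only the wider peaks of both lists, taken as above, it was 30.2, with 6 members in both and 1 in Ctrl only. Without peaks whose ends both fell on a 10-base grid it was 20.3, with 7 in both and 2 in Ctrl only. All 15 erasers and readers had peaks in both libraries, at percentile 62.8. When peaks whose ends both fell on a 10-base grid were left out, it was 98.2, with 13 in both and 2 in Cas only. With only the wider peaks it was 59.2, with 12 members in both, 1 in Ctrl only and 1 in Cas only. The demethylases FTO and ALKBH5 had 2 and 3 in each. YTHDF1 had 1 in each, YTHDF3 2 in Ctrl and 1 in Cas, YTHDC1 2 and 3, and YTHDC2 3 and 5. IGF2BP1 had 6 in each, IGF2BP2 and IGF2BP3 3 in each, ELAVL1 2 in each, PRRC2A 5 and 6, and FMR1, HNRNPA2B1 and HNRNPC 1 in each.

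Cytosolic ribosomal proteins leaned towards Cas. Of 87 members 56 had a peak, 38 in both, 12 in Cas only and 6 in Ctrl only, at percentile 99.9. RPL7A, RPL36AL and RPS6 were the Cas-only members with the widest peaks, of 169, 157 and 154 bp. Many processed pseudogenes resemble these genes, and how reads shared with them were treated is not given in the sources used here. With only the wider 50% of each list, 8 members had a peak and the percentile was 59.9, and without peaks whose ends both fell on a 10-base grid it was 99.99. Zinc finger genes of the ZNF series leaned towards Ctrl, with 379 of 518 having a peak, 320 in both, 46 in Ctrl only and 13 in Cas only, at percentile 0.46. ZNF549 and ZNF572, the Ctrl-only members with the widest peaks, had 3 peaks each. ZNF547, the Cas-only member with the widest peak, had 2. These members were chosen by width and are not those with most peaks. The percentile was 8.49 without the grid peaks and 0 with the wider 50%, where 81 members were in Ctrl only and 22 in Cas only. On the 52 ribosomal protein and 340 zinc finger genes with a single GENCODE partner, the percentiles were 99.5 and 1.71 without and 96.2 and 11.0 with matching of the random lists on transcript length. DNA repair genes had 76 peaks in Ctrl and 92 in Cas. Of its 24 members 22 had peaks in both libraries. ATM and ATR had 3 and 8 peaks each, ATR over 1265 bases in Ctrl and 1178 in Cas, while BRCA2 had 8 and 8 and RAD50 4 and 4.

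In the full lists the other lists lay within the central range of random lists. Chromatin and transcription co-regulators had peaks at 40 of 41 members, all in both libraries, with CHD7 at 6 and 7 and TET3 at 7 and 6. Glycolysis had 11 of 17, all in both, with HK2 at 2 and 4 and PKM at 2 and 3. Immediate early genes had 16 of 24 in both, led by FOSL2 and KLF6. The unfolded protein and integrated stress response had 17 of 19 in both, led by TRIB3 and HSPA5. RNA decay and deadenylation had 27 of 29 in both, led by SMG6 and TOB2, and heat shock proteins 12 of 13 in both, led by HSPA1B, which is nearly identical to HSPA1A, and HSF1. Of 34 cell cycle genes, 32 had peaks in both, CCND3 in Ctrl only and PLK1 in Cas only. Of 24 splicing factors 23 had them in both and HNRNPM in Ctrl only. Of 15 p53 targets 13 had them in both and BBC3 in Ctrl only. Interferon and RNA sensing genes had peaks at 11 of 26, with IRF3 and IRF1 in Ctrl only. Notch and Wnt genes had 23 of 27 in both and DVL3, TCF7L2 and FZD5 in Ctrl only, at percentile 5.79. With only the wider peaks of both lists, taken as above, it was 64.0, with 4 members in Ctrl only and 4 in Cas only. Without the grid peaks it was 42.8, with 2 in Ctrl only and 1 in Cas only. The nuclear-encoded respiratory chain had 18 of 29 in both, NDUFV1, SDHB and COX5A in Cas only and NDUFA2 in Ctrl only. Its percentile was 95.1, or 98.5 without the grid peaks. With only the wider peaks it was 45.55, with 3 members in Ctrl only and 2 in Cas only. No marker of blood cells had a peak among 11. Of 11 markers of liver, muscle and neurons SYT1 had peaks in both and RBFOX3 in Ctrl only, and of 10 markers of fibroblasts and endothelium COL1A1 had peaks in both. No mitochondrially encoded gene was matched in the annotation used.

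Peaks starting in the first 100 nt of a transcript made up 2.70% of Ctrl (2.51 to 2.92) and 2.23% of Cas peaks (2.05 to 2.43), and 68.4% and 82.6% of them were overlapped by a peak of the other library. On the 1859 transcripts with a matching 5' end, 22.9% of 3744 Ctrl peaks (21.6 to 24.3) and 22.6% of 3587 Cas peaks (21.3 to 24.0) lay within 200 nt of the stop codon, against 10.7% and 11.0% when shuffled. The coding sequence outside that window held 47.1% of the Ctrl peaks and 1794 of the Cas peaks (48.4 to 51.6%), against 44.5% and 44.8% when shuffled. The 3' UTR held 20.2% and 19.5%, below the shuffled 34.6% and 35.1%, and the 5' UTR 3.26% and 2.70%. DRACH occurred in 97.6% of Ctrl and 97.5% of Cas peaks, where shuffled peaks had it in 95.1% and 94.9%. The stricter GGACT was found in 29.2% of Ctrl (27.8 to 30.7) and 27.9% of Cas peaks (26.4 to 29.3), against 18.9% and 18.7% when shuffled. The Ctrl and Cas intervals for GGACT and for the stop codon window overlapped.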

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

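Alternatives without the 10-base grid, over all GENCODE partners and with a moved coding start were chosen after seeing the data; the others were planned. Of the planned values 32 moved beyond their interval or by over 1.5 times and 17 did not, and of the added ones 8 did and 11 did not. No paired analysis was possible because each group had 1 library. Ignoring strand, whole gene bodies with introns and 1 transcript per gene were not run, since positions run along transcripts, all on the plus strand, and all but 3 of the 11250 genes had 1 transcript. With a reciprocal overlap of 50%, the shared part was 62.9% of Ctrl and 64.2% of Cas peaks. Using the wider 50% of both lists gave 65.2% and 66.7%, and of the list asked about only 88.6% and 88.4%. Merging peaks within 100 bp gave 76.8% and 79.1%, and leaving out grid peaks 70.3% and 73.7%. The wider 50% of both lists, which hold fewer peaks by construction, had 1525 genes in Ctrl only, 1162 in Cas only and 5904 in both, no YTHDF2 peak in Ctrl or Cas (0 and 0) and 2 SPEN peaks in Ctrl against 5 in Cas, the reverse of the order in the full lists. In that set the 5' UTR held 1.74% of Ctrl and 2.06% of Cas peaks, the coding sequence 52.0% and 54.1% and the 3' UTR 17.4% and 15.8%, and DRACH was in 99.5% and 99.5%. With no stop codon window the coding sequence held 59.7% and 62.3% and the 3' UTR 30.5% and 29.9%. Over all partners the 5' UTR held 4.06% and 3.54%, the 3' UTR 22.1% and 21.6% and the Ctrl coding sequence 48.8%. Within 50 nt of the peak centre DRACH was in 92.6% and 92.4% of peaks. Searched inside whole peaks, GGACT alone was in 29.2% and 27.9%. Counted from the transcript start, the labelled position lay 358 and 361 nt from the nearest YTHDF2 peak and 35 nt from the nearest Ctrl peak at SPEN, which lay 396 nt away with the coding start moved. For overlap and target peaks the cause of these moves was not tested. Depth limits these lists to an unknown degree, since they hold no read counts.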

Other observations

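The tests on peak width, on GGACT, on lncRNAs, on whole genes and on length among genes with 1 peak were chosen after the values they measure had been seen. The others were chosen before, although the transcript set of the length tests was widened after its first results. A condition that the prediction did not hold was also added to the test of the ratio by length. Among genes with peaks in both libraries the mean change in peak number showed no steady trend with length, with values from 0.030 to 0.065 more peaks in Cas over the 4 classes.

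Peaks without a partner were narrower than overlapped ones, with medians differing by -67 bp in Ctrl and -52 bp in Cas. On the transcripts with a matching 5' end, GGACT was found in 21.6% of 966 Ctrl and 18.9% of 790 Cas peaks without a partner. Both shares were above the highest of 100 shuffles (17.4% and 18.0%), with a small margin in Cas. These transcripts were chosen after motif profiles were seen to be sharper on them, and the shuffles did not keep peaks in their transcript region. The shares therefore cannot decide whether calls away from m6A sites were the source. Peaks near the calling limit remain a candidate explanation, which the difference in width cannot decide. A wider peak is overlapped more often by position alone, and no shuffle was made within width groups. A difference between the groups stays open, because 1 library per group cannot show whether such a peak recurs.

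List size alone did not account for the excess of Ctrl-only genes, since lists with the same number of widest peaks gave a ratio of Ctrl-only to Cas-only genes of 1.83, although in the wider 50% of both lists it was 1.31 against 2.09 in the full lists. Loss of Ctrl peaks 1 by 1 at rates set by their width is argued against. Of the genes with 3 or more Ctrl peaks, 100 had none in Cas. That was 3.00 times the 33.4 given by the loss rate of all Ctrl peaks in each of 10 width classes. It was 7.89 times the 12.7 given by a single rate from transcripts with peaks in both lists, which leaves out genes that lost every peak. The expected numbers count every gene whose peaks all lack a partner. They so include genes with peaks of the other library elsewhere, which the observed numbers leave out. This difference cannot produce the excess in Ctrl, but the reverse count of 14 against 22.1 cannot be read as a deficit. Rates that differ between genes for other reasons stay open. The ratio was 5.16 times higher in the longest class than in the shortest (95% bootstrap interval 3.49 to 8.60, and 5.74 in the transcript set first used). That met the bound fixed beforehand for a greater loss of longer transcripts. A condition absent from that prediction was added, that the Ctrl-only share itself rise with length, and this share fell from 12.9% to 6.64%. Among genes with 1 Ctrl peak the share without a Cas peak was 5.84 percentage points higher in the longest class with overlapping intervals (18.7 to 27.7% against 15.3 to 18.9%). Among genes with 1 Cas peak the share without a Ctrl peak was 15.9% (14.2 to 17.7) in the shortest class and 7.28% (4.90 to 10.7) in the longest. Length stays open, because the added condition was not met and the intervals for genes with 1 Ctrl peak overlapped. Length could carry part of the lean of the gene lists, since matching on it moved ribosomal proteins from percentile 99.5 to 96.2 and zinc finger genes from 1.71 to 11.0 on the same members (94.3 and 6.77 with matching in the set first used). Scarce transcripts missed in Cas may be involved, as the lncRNA share was 4.95 percentage points higher among Ctrl-only genes, but without read counts abundance, depth and the groups themselves stay open. Among protein-coding genes alone 933 were in Ctrl only and 478 in Cas only, a ratio of 1.95 against 2.09 in the full lists. The lncRNAs alone therefore did not account for the excess, although 129 of them were in Ctrl only and 35 in Cas only.

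METTL14 had its single peak in Ctrl only, and 1 hypothesis was that the transfected construct held METTL14 sequence, which the labels do not say. The test fixed beforehand took a loss rate above 5% among genes with 1 Ctrl peak as speaking against it, and the rate was 19.0% (17.9 to 20.2), so that bound was exceeded. The bound was poorly chosen: a loss rate over other genes shows that losing a sole peak was common and cannot exclude construct sequence at METTL14. No read counts over METTL14 or the construct were used, and the hypothesis cannot be told apart from the common loss of single peaks.

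Peaks with both ends on a 10-base grid made up 27.2% of Ctrl and 28.9% of Cas peaks. They were 50.2% and 49.6% of the peaks without a partner, and 19.9% and 23.1% of the overlapped ones.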
